A study of Homo sapiens with 26 samples.

How the data were processed

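ATAC-seq was made from 13 T-47D clones of 3 ESR1 genotypes and 2 labs, each with DMSO and with E2, giving 26 libraries in 12 groups. Groups and clone numbers were taken from the labels. Libraries of a group are separate clones, so the spread measured is between clones.

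Each library came with a peak list and a coverage track. Bowtie, MACS2 and DESeq2 and the builds hg19 and GRCh37 are named in the submitters' processing notes, without roles or versions. The peak lists were deposited per library. They give a score per peak, a fold enrichment as a ratio over background, and the −log10 of the p-value and q-value per peak, all as the authors deposited them. The lowest −log10 p in a library lay between 10.0 and 11.4. These values are the authors'. The p-values served to choose the strongest summit of each region, which placed the 500 bp windows. The q-values served to filter peaks in an alternative. The coverage tracks are signal as deposited by the authors: by their values a pileup of tags extended to 1 length per library and normalized to the number of tags. The steps of a track gave the depth, 1399208 to 10760788 tags. The extension was 80 to 88 bp in the Gertz and 97 to 154 bp in the Oesterreich libraries, which spreads tags differently over a region. It also followed genotype in the Oesterreich libraries: 154 bp in both WT DMSO libraries, 123 and 116 bp in WT with E2, 100 to 111 bp in the mutants with DMSO and 97 to 114 bp in the mutants with E2. Recovering fragments from the steps returned at least 99.99% of the tags.

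Peaks on the 22 autosomes and X, 442157 over all chromosomes, were merged where they overlapped by at least 1 bp into 44326 regions, of which the 36240 with a peak in at least 2 libraries were tested (median width 220 bp). Mean coverage was scaled by the median of ratios, and log2 of it plus a pseudocount of 0.153 (0.1 of the median) was fitted with limma 3.58.1 (R 4.3.3), with a mean-variance trend, over all 26 libraries with the 12 groups as terms, so that comparisons share 1 estimate of the spread. Log2 differences are on that scale and understate changes of low regions. Contrasts weighted both labs equally. Regions were called at a Benjamini-Hochberg adjusted p under 0.05, and all tests are two-sided. Without any change, a share of 0.05 of the 36240 tested regions would on average have an unadjusted p under 0.05. A count below that share marks a comparison whose p-values run high. Extraction used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.

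The procedure was tested on simulated fragment counts in 500 bp windows at the 36240 regions, with the same dispersion of 0.0175 throughout. These are not the mean coverages of whole regions that the main fit used. For E2 in WT 97.0% of regions changed by 4-fold were recovered, 53.7% at 2-fold and 1.49% at 1.5-fold. For Y537S against WT these were 100%, 46.3% and 2.99%, and for D538G 97.0%, 55.2% and 5.97%. Changes of 1.5-fold were therefore mostly not detectable in this simulation. Recovery at the regions of lowest coverage, or with the real differences between labs and clones, was not tested. These shares are thus not the power of the real comparisons over all regions.

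Sets were tested with fry (self-contained) and camera (preset correlation 0.01, and an estimated correlation), and their p-values were adjusted within each family of sets and comparisons. The E2-gained regions were defined in the WT clones numbered 1 and the mutants compared with those numbered 2, since both comparisons otherwise share WT libraries. In these divided fits each WT group held 1 library, so the spread came from the mutant clones. The p-values of these fits do not hold the variation between WT clones. Unchanged groups were simulated 20 times. Named regions were those past the threshold with the same sign in both labs: the 10 largest rises and falls in the E2 response of WT and in each mutant against WT without E2, and the first 3 each way elsewhere. The design, this rule and the alternatives were fixed before the data were examined, except those the closing section names.

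DMSO and E2 libraries with the same number come from the same clone by their labels. Their deviations from the group means correlated with r between -0.006 and 0.40, over 0.1 in 9 of 13 clones. In a group of 2 clones both give the same r by construction, so these values are not independent. Alternatives were other scalings, pseudocounts of 0.01 and 0.5 of the median, leaving out the lowest 25% by coverage, peaks of at least 6 libraries, a −log10 q of at least 10, 500 bp windows, array weights, a correction by coverage outside peaks in 1 Mb windows, the replicate block, each lab alone, only the libraries compared, and each library left out.

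The fixed gene lists and motif searches were not run, because annotation and sequence of hg19 were not used here. GC content was not analysed here for the same reason.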

Results

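Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open DNA and leaves the more accessible stretches with more sequenced tags. The cells were T-47D, an estrogen receptor positive breast cancer line, carrying wild-type ESR1, the gene for estrogen receptor alpha (WT), or the receptor mutations Y537S or D538G. Clones came from 2 laboratories, named Gertz and Oesterreich in the labels. After 5 days in hormone-depleted medium each clone received 0.1% DMSO or 10 nM 17beta-estradiol (E2) for 1 h. The 26 libraries fell into 12 groups of lab, genotype and treatment, with 2 clones per group and 3 in each Oesterreich D538G group. Clones of a group were separate clones by their labels. Depth ran from 1399208 to 10760788 tags per library. The number of peaks ran from 2360 to 32649. The share of coverage inside the 36240 consensus regions was 32.6% to 41.3% in the Gertz libraries, 17.0% to 22.2% in the Oesterreich WT and Y537S libraries and 10.1% to 13.4% in the Oesterreich D538G libraries. Positions are on hg19, and regions are named by position because gene annotation of that build was not used here.

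**Figure D1:**
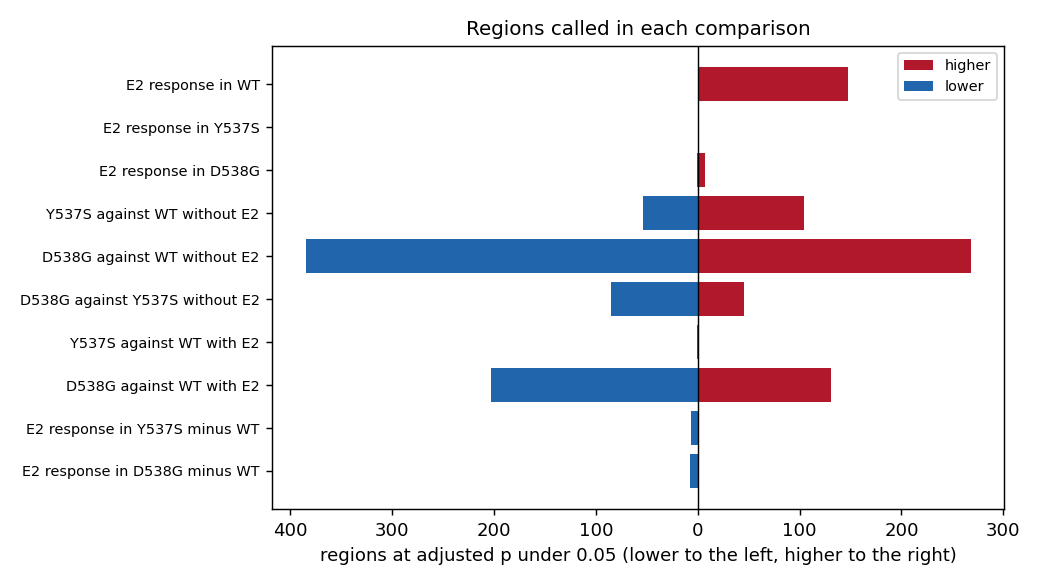
Number of regions (horizontal axis) past the adjusted p threshold of 0.05 in each comparison (vertical axis), with higher regions to the right of 0 and lower regions to the left. E2 in WT gave 148 higher and 0 lower regions, and D538G against WT without E2 gave 268 higher and 385 lower.

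The first question was which regions opened or closed after 1 h of E2 in WT cells. Accessibility rose at 148 of 36240 regions and fell at 0 with limma, with 1380 at an unadjusted p under 0.05 and a median log2 rise of 1.83 among those called. Of the regions named by rule, that on chromosome 2 from 11679570 to 11679903 had the largest rise, a log2 difference of 2.97 (SE 0.24). Its scaled coverage went from 0.239 ± 0.135 (SD, n = 4) to 2.998 ± 1.26 (SD, n = 4). Scaled coverage is the tag pileup normalized to the number of tags and then scaled by the median of ratios. On chromosome 17 from 38478578 to 38478860 the level went from 0.460 ± 0.309 to 5.10 ± 3.81 (SD, n = 4 each) (log2 difference 2.87, SE 0.19). The Gertz clones with E2 stood there at 8.67 and 8.10 and the Oesterreich clones at 2.17 and 1.47. Rises of similar size were found on chromosome 9 from 33221271 to 33221578, with a log2 difference of 2.96 (SE 0.34), and on chromosome 17 from 48862591 to 48862913, with 2.79 (SE 0.35). The other named regions lay on chromosomes 10, 14, 1, 9, 6 and 10 and had log2 differences of 2.67 to 2.78.

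All 148 regions were higher with E2 in the Gertz clones and 147 were higher in the Oesterreich clones, when each lab was compared with its own DMSO libraries. The mean rise was 2.45 in the Gertz clones and 1.21 in the Oesterreich clones on the log2 scale. A peak had been called by the authors at 12.3% ± 6.7 (SD, n = 4) of these regions in WT with DMSO and at 61.1% ± 21.5 (SD, n = 4) with E2, where the shares over all regions were 41.0% ± 13.5 and 48.9% ± 12.2 (SD, n = 4 each). Of the 148, 43 had a peak in 2 to 6 libraries, as did 13411 of the 36240 tested. A peak in all 26 was found at 2 of them, as at 1623 of those tested, and these shares were not compared by a test. Array weights called 237 regions, all higher, and limma voom on recovered fragments 242 higher and 1 lower. Leaving out Gertz WT E2 replicate 1 gave 79 regions, leaving out Gertz WT DMSO replicate 2 or Oesterreich WT E2 replicate 1 gave 95 each, and the Oesterreich clones alone gave 11.

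The same exposure was compared in the mutant clones. In Y537S 0 regions passed the threshold with limma, against 323 at an unadjusted p under 0.05. That is below the share of 0.05 of tested regions that no change would give, as were the 1380 in WT. The p-values of these comparisons thus ran high, and the 0 does not show that no region responded. limma voom on recovered fragments called 25, all higher, and array weights called 9, all higher. In D538G 7 regions rose and 1 fell, with 2216 at an unadjusted p under 0.05, and with the clone as a block 18 rose and 2 fell. When only the D538G libraries were fitted, 0 regions passed with limma, against 922 at an unadjusted p under 0.05, while limma voom on recovered fragments called 91. On chromosome 16 the stretch from 83980556 to 83981039 rose in D538G by 1.67 (SE 0.21, adjusted p = 0.00141) on the log2 scale. The 1 lower region was on chromosome 17 from 43248356 to 43248538, where accessibility fell by 0.97 (SE 0.17, adjusted p = 0.0463). Leaving out any 1 of the 4 Gertz D538G libraries left 1 region. The count was 36 (32 higher, 4 lower) without Oesterreich D538G DMSO replicate 2 and 47 (42 higher, 5 lower) without Oesterreich D538G E2 replicate 3. Without Oesterreich D538G E2 replicate 1 it was 54, with 19 higher and 35 lower, so that the direction turned. The Oesterreich clones alone gave 23 higher and 23 lower.

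Although few single regions were called, the 148 regions gained with E2 in WT moved together in the mutants. With E2 their mean log2 difference was 0.67 in Y537S, with all 148 regions on the higher side (fry adjusted p = 0.000732), and 0.89 in D538G, with 147 on the higher side (fry adjusted p = 3.29e-05). Camera with an estimated correlation gave an adjusted p = 0.000142 for Y537S and 0.00019 for D538G. Adjusted over the list alone, 43 regions were higher in Y537S and 126 in D538G, against 0 and 5 when adjusted over all regions. The list had been selected from the WT libraries of the same series.

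The E2 responses were then tested against each other. By construction this difference is the difference from WT with E2 minus that without E2, so it is not separate from those results. The response was smaller than in WT at 7 regions in Y537S and at 8 regions in D538G, and larger at 0 regions in both limma tests. At an unadjusted p under 0.05 there were 430 and 1347 regions. Both counts are below the share of 0.05 that no change would give, so the p-values of these comparisons also ran high. Array weights called 26 lower regions in Y537S, and limma voom on recovered fragments called 21, with 0 higher. That on chromosome 17 from 38478578 led both lists, with differences of -2.36 (SE 0.27, adjusted p = 0.000122) and -2.33 (SE 0.26, adjusted p = 7e-05). Over the 148 regions the mean difference in response was -1.16 for Y537S and -0.94 for D538G (fry adjusted p = 0.00011 and 0.000488). With an estimated correlation the adjusted p was 4.62e-05 and 0.000611. These regions had been selected on the same WT libraries, so part of this difference can come from the selection. At 30 regions defined in the WT clones numbered 1, the response of the mutants minus that of the WT clones numbered 2 was -1.31 for Y537S, lower at all 30, and -1.05 for D538G, lower at 27 (fry adjusted p = 0.000705 and 0.00214). With an estimated correlation the adjusted p was 0.000512 and 0.00458. With the clone numbers exchanged the means over 25 regions were -1.435 and -1.22, and 24 of the 25 were lower in each mutant. With the clone as a block 13 regions were lower in Y537S. When only the libraries compared were fitted the counts were 14 and 2. For Y537S the count was 13 without Gertz WT DMSO replicate 1 and 4 without Gertz Y537S DMSO replicate 2 or Gertz WT E2 replicate 1. For D538G it was 16 without Gertz WT DMSO replicate 1, 5 without Oesterreich WT DMSO replicate 2, 3 without Gertz D538G DMSO replicate 2 or Oesterreich WT E2 replicate 1, and 2 without Gertz WT DMSO replicate 2, Gertz D538G DMSO replicate 1, Gertz WT E2 replicate 1, either Gertz D538G E2 library, Oesterreich WT DMSO replicate 1 or Oesterreich WT E2 replicate 2.

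The next question was how the mutant clones differed from WT in the absence of hormone. In Y537S 104 regions were more accessible and 54 less accessible than in WT. Chromosome 11 from 70652056 to 70652433 was the most raised of the named regions, at 2.48 ± 0.79 against 0.157 ± 0.070 scaled coverage (SD, n = 4 each), a log2 difference of 3.06 (SE 0.32). On chromosome 5 from 154448241 to 154448762 the levels were 3.50 ± 0.82 and 0.567 ± 0.307 (SD, n = 4 each), and WT with E2 stood at 3.75 ± 0.81 (SD, n = 4). Of the 10 most raised regions, those starting at 11679570 on chromosome 2, 106240671 on chromosome 10, 38478578 on chromosome 17 and 33221271 on chromosome 9 were also among the 10 with the largest rise under E2 in WT, a comparison with the same WT DMSO libraries, which can place a region in both lists. Among lower regions, the largest fall was on chromosome 20 from 35500077 to 35500310, from 1.60 ± 0.471 in WT to 0.434 ± 0.463 in Y537S (SD, n = 4 each), a log2 difference of -1.95 (SE 0.31). The fall there was -1.07 in the Gertz clones and -2.84 in the Oesterreich clones.

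In D538G 268 regions were more accessible and 385 less accessible than in WT. The largest rise was on chromosome 3 from 9988949 to 9989117, from 0.0503 ± 0.0600 (SD, n = 4) to 1.842 ± 1.505 (SD, n = 5), with log2 differences of 4.43 in the Gertz and 1.51 in the Oesterreich clones. The region on chromosome 17 from 38478578 to 38478860 stood at 3.28 ± 1.32 (SD, n = 5) in D538G against 0.460 ± 0.309 (SD, n = 4) in WT, a log2 difference of 2.63 (SE 0.18), with 2.55 in the Gertz and 2.71 in the Oesterreich clones. On chromosome 17 the region from 48862591 was higher by 2.73 (SE 0.33). On chromosome 10 from 79596137 to 79596304 the log2 difference was 3.85 in the Gertz and 0.66 in the Oesterreich clones. The Oesterreich WT clones stood there at 0 and 0.73 and the Oesterreich D538G clones at 0.25, 0.67 and 0.43. The Oesterreich rise at this region thus rested on 1 WT library. On chromosome 11 from 3028236 the log2 difference was 3.91 in the Gertz and 0.98 in the Oesterreich clones. The largest fall was on chromosome 2 from 218764814 to 218765028, from 2.04 ± 0.70 (SD, n = 4) to 0.281 ± 0.245 (SD, n = 5), with log2 differences of -2.45 in the Gertz and -2.36 in the Oesterreich clones. On chromosome 15 44 regions were higher and 0 lower. On chromosome 12 4 were higher and 52 lower, and on chromosome 14 3 were higher and 36 lower. Coverage outside peaks also differed on these chromosomes: in both Gertz D538G clones the log2 difference from WT was 0.54 on chromosome 15, -0.30 and -0.32 on chromosome 12 and -0.35 and -0.38 on chromosome 14. In the 3 Oesterreich D538G clones it was 0.18, 0.40 and 0.40 on chromosome 15, 0.14, -0.05 and -0.08 on chromosome 12 and -0.05, -0.10 and 0.31 on chromosome 14.

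Both mutant counts moved with single libraries and with the spread used. When only the libraries compared were fitted, 1111 regions were called for Y537S and 65 for D538G. Array weights called 1539 and 1309, and limma voom on recovered fragments 1666 and 1494. Without Gertz WT DMSO replicate 1 or 2 the Y537S count was 356 or 39, without Oesterreich WT DMSO replicate 1 or 2 it was 56 or 86, without Gertz Y537S DMSO replicate 1 or 2 it was 59 or 35, and without Oesterreich Y537S DMSO replicate 1 or 2 it was 53 or 39. The D538G count was 131 without Gertz WT DMSO replicate 2, 133 and 127 without Gertz D538G DMSO replicate 1 and 2, and 284 and 243 without Oesterreich WT DMSO replicate 1 and 2. Scaling by total coverage moved the median of all regions by -0.25 in Y537S and -0.56 in D538G on the log2 scale, and turned the split of higher against lower regions to 220 against 3402 in Y537S and 203 against 16983 in D538G. Under the median of ratios, to which the reported differences are relative, these medians were 0.00 and -0.03. With quantile normalization the Y537S split was 307 against 313.

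**Figure D2:**
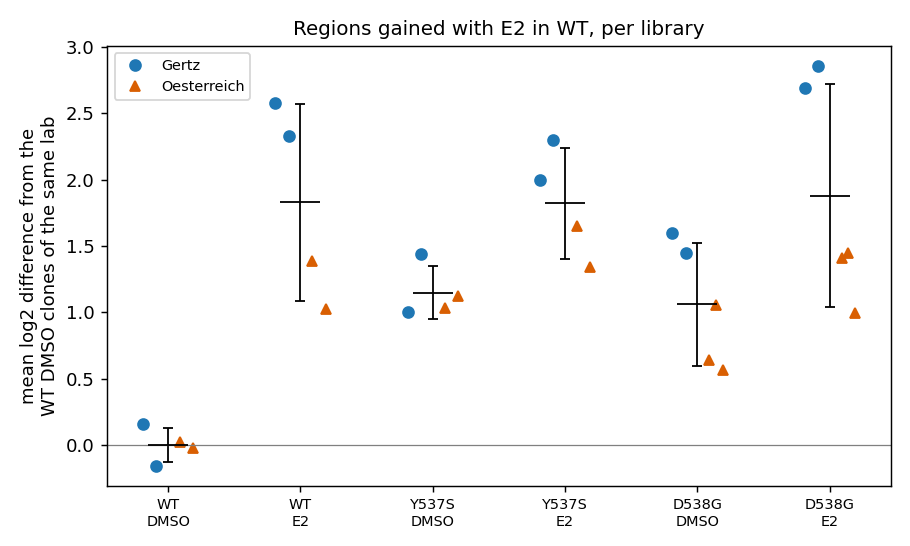
Mean log2 difference (vertical axis) of the 148 regions gained with E2 in WT, for each library by genotype and treatment (horizontal axis), relative to the WT DMSO clones of the same lab. Bars are the mean and SD over libraries. The mutants without E2 averaged 1.15 (Y537S) and 1.06 (D538G), and WT with E2 averaged 1.83.

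The regions gained with E2 in WT were examined in the mutants without hormone. They were more open than in WT in all 9 mutant clones. So that the regions and the comparison used different WT clones, 30 regions were defined in the WT clones numbered 1 and the mutants were compared with the WT clones numbered 2. The spread in this fit came from the mutant clones, so its p-values leave out variation between WT clones. The mean log2 difference was 1.53 in Y537S and 1.45 in D538G, and all 30 regions were higher in both (fry adjusted p = 1.16e-05 and 1.32e-05). The E2 response of the WT clones numbered 2 at the same regions was 1.96. Per clone the difference was 1.34 and 1.87 in the Gertz Y537S clones, 1.42 and 1.49 in the Oesterreich Y537S clones, 1.91 and 1.82 in the Gertz D538G clones and 0.94, 1.31 and 0.87 in the Oesterreich D538G clones. With an estimated correlation camera gave an adjusted p = 0.00104 for Y537S and 0.00145 for D538G. Exchanging the clone numbers gave 25 regions with means of 1.38 and 1.27, and 24 of the 25 were higher in each mutant. Alternatives redefined the regions each time, in sets of 3 to 126 regions, so their means cover other regions. With a pseudocount of 0.5 of the median the means of the first division were 0.90 and 0.86. With regions defined in the Oesterreich WT clone numbered 1 alone, the Y537S mean in the Oesterreich clones was 2.37. That value is not comparable with the 1.42 and 1.49 of those clones at the 30 regions.

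Without the split, the mean over all 148 regions, with both labs weighted equally, was 1.15 in Y537S and 1.14 in D538G, where simulated unchanged groups gave 0.47 and 0.48. Adjusted over the list alone, 119 regions were higher in Y537S and 126 in D538G, against 57 and 71 when adjusted over all regions. The list was selected with the same WT DMSO libraries, so part of these counts can come from the selection. With E2 in both genotypes, the mean difference from WT was -0.01 in Y537S (fry adjusted p = 0.983) and 0.20 in D538G (fry adjusted p = 0.293). The 148 regions had been selected for high coverage in these WT E2 libraries, which lowers the difference, so values near 0 do not show equality. At the 30 regions defined in the WT clones numbered 1 and measured against those numbered 2, the means were 0.22 and 0.40 (fry adjusted p = 0.534 and 0.251), with 22 and 27 regions on the higher side. With the clone numbers exchanged they were -0.05 and 0.05 over 25 regions (fry adjusted p = 0.867 for each). The difference in E2 response given above is by construction this difference with E2 minus that without E2. At the 30 regions the mutants stood 1.53 and 1.45 above WT without E2, and 0.22 and 0.40 above it with E2. Under the median of ratios the smaller E2 response there thus lay in the higher level without E2. A lower level with E2 is not excluded, because that level depends on the scaling. Total coverage scaling moved the median of all regions with E2 by -0.17 in Y537S and -0.60 in D538G. Over the 148 regions, camera with the preset correlation called the D538G value with E2 (adjusted p = 1.06e-05) and with an estimated correlation gave an adjusted p = 0.337. A peak had been called at 44.4% (range 33.8% to 60.8%, n = 4) of these regions in Y537S with DMSO and at 28.1% ± 30.8 (SD, n = 5) in D538G with DMSO, the latter being 60.5% in the Gertz clones and 6.5% in the Oesterreich clones. Over all regions a peak had been called at 56.3% ± 10.3 (SD, n = 4) in Y537S and 36.3% ± 28.9 (SD, n = 5) in D538G, with 65.3% in the Gertz and 17.0% in the Oesterreich D538G clones.

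In the reverse direction, regions called in the mutants against the WT clones numbered 2 were measured for an E2 response in the WT clones numbered 1. As a set, the 58 regions higher in Y537S had a mean E2 difference of 1.085 ± 1.12 (SD over regions) on the log2 scale, with 46 on the higher side (fry adjusted p = 6.01e-05). The 151 higher in D538G had 0.52 ± 0.94 (SD over regions), with 101 on the higher side (fry adjusted p = 0.000246). The sets were also divided by the E2 response of the WT clones numbered 2, which were not used to measure them. The 22 regions of each set that were E2-gained in those clones had means of 1.94 and 1.90. The other 36 had 0.56 for Y537S, with 25 higher (fry adjusted p = 0.00116), and the other 129 had 0.28 for D538G, with 80 higher (fry adjusted p = 0.00563). The 48 D538G regions that were not higher with E2 in those clones even at an unadjusted p under 0.05 had a mean of 0.02 (fry adjusted p = 0.837). With the clone numbers exchanged the sets held 16 and 24 regions with means of 1.81 and 1.33, and the 11 D538G regions that were not E2-gained did not pass (mean 0.21, fry adjusted p = 0.271), while the 6 for Y537S did (mean 1.09, with 4 higher, fry adjusted p = 0.000199). The 5 regions lower in Y537S had a mean of -0.04 and the 60 lower in D538G had -0.02, and neither set passed (fry adjusted p = 0.792 for each).

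**Figure D3:**
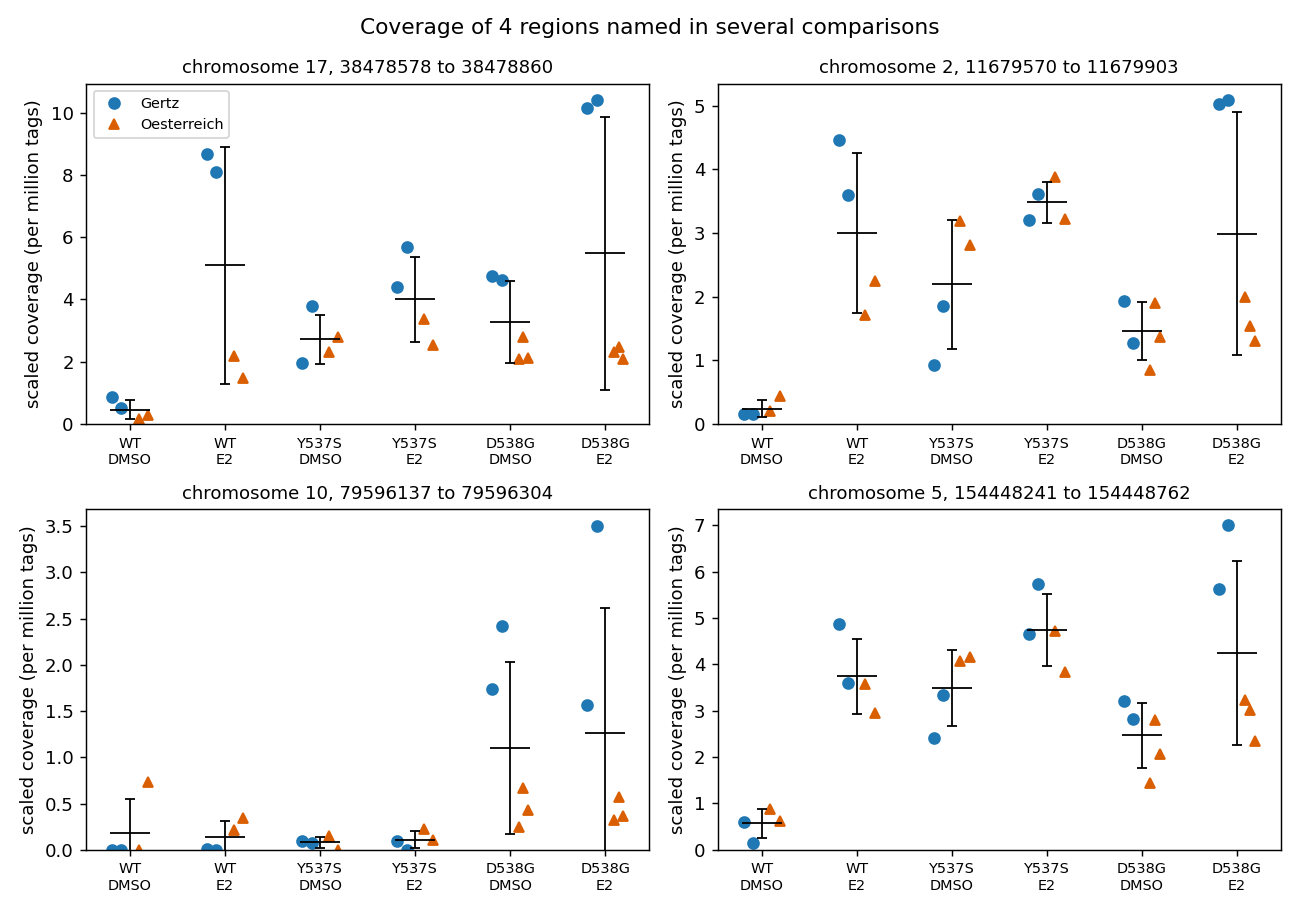
Scaled coverage (vertical axis) of 4 regions named in several comparisons, for each library by genotype and treatment (horizontal axis). It is the tag pileup normalized to the number of tags and then scaled by the median of ratios. Circles are Gertz clones, triangles Oesterreich clones and bars the mean and SD, clipped at 0. On chromosome 17 from 38478578 the WT DMSO mean was 0.460 and the D538G DMSO mean 3.28.

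The 2 mutations were compared with each other directly. Without E2 45 regions were more accessible in D538G than in Y537S and 85 less. On chromosome 8 from 140498185 to 140498457 D538G stood at 0.829 ± 0.567 (SD, n = 5) and Y537S at 0.0384 ± 0.0300 (SD, n = 4), and on chromosome 16 from 58686724 to 58686850 the levels were 0.0315 ± 0.0704 (SD, n = 5) and 0.903 ± 0.686 (SD, n = 4). At the 148 E2-gained regions the mean difference was -0.01 (fry adjusted p = 0.928). When only the libraries compared were fitted 17 regions were called, and the Gertz clones alone gave 2. Without Gertz Y537S DMSO replicate 1 or 2 the count was 13 or 20, without Gertz D538G DMSO replicate 1 or 2 it was 26 or 11, without Oesterreich Y537S DMSO replicate 1 or 2 it was 30 or 14, and without Oesterreich D538G DMSO replicate 3 it was 335. The split was 56 higher against 3022 lower with total coverage scaling, which moved the median by -0.31, and 117 against 100 with the correction for coverage outside peaks.

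Both mutants shared 60 regions above WT and 14 below, with 0 changed in opposite directions. Independent lists of these sizes would share 0.769 and 0.574, and simulated unchanged groups with the same WT libraries shared 0 of each. The simulation holds no effects, so it does not show what the shared WT libraries add to lists of these sizes. With the WT clones divided between the mutants, 13 regions were shared above WT and 0 below, or 12 and 0 with the clone numbers exchanged. The lists of raised regions in the divided fits were shorter than in the main fit for both mutants. The 13 and 12 are therefore not comparable with the 60. The covariance of the log2 differences was 0.110, against 0.0528 in the simulation, a difference of 0.0574. Of the 60 shared raised regions 45 were E2-gained in WT, a list that shares the WT DMSO libraries. With E2-gained regions defined in the WT clones numbered 1 and both mutants compared with those numbered 2, 16 of 49 were E2-gained, and with the numbers exchanged 8 of 10, where independent lists would share 0.0406 and 0.00690. The total of 74 shared regions became 167 without Gertz WT DMSO replicate 1, 21 without replicate 2 of that group or without Gertz Y537S DMSO replicate 2, 38 without Gertz Y537S DMSO replicate 1, 31 and 34 without Gertz D538G DMSO replicate 1 and 2, 32 and 37 without Oesterreich WT DMSO replicate 1 and 2, and 32 and 24 without Oesterreich Y537S DMSO replicate 1 and 2. Total coverage scaling gave 97 shared above and 3190 below, limma voom on recovered fragments 153 and 296, and the Oesterreich clones alone 161 and 281. With array weights 225 were shared above and 137 below, and with quantile normalization 122 and 43.

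In the presence of E2 Y537S differed from WT at 1 region, on chromosome 11 from 44598769 to 44599119, which was lower by a log2 difference of -0.98 (SE 0.14, adjusted p = 0.0123), while 2841 regions had an unadjusted p under 0.05. It stood at 2.30 ± 0.845 in Y537S and 4.53 ± 0.852 in WT (SD, n = 4 each). The count was 0 without Gertz WT E2 replicate 1, Gertz Y537S E2 replicate 1, Oesterreich WT E2 replicate 1 or Oesterreich Y537S E2 replicate 2 with limma, with 1847 to 2330 regions at an unadjusted p under 0.05, and 2 without Gertz WT E2 replicate 2 or Oesterreich Y537S E2 replicate 1. It was 514 when only the libraries compared were fitted, 714 with array weights, 1739 with limma voom on recovered fragments, 15 higher and 303 lower with total coverage scaling and 140 higher and 238 lower with quantile normalization. D538G with E2 had 131 higher and 203 lower regions. Accessibility on chromosome 8 from 140498185 was raised by 2.42 (SE 0.39) and that on chromosome 4 from 13954861 to 13954978 was lower by a log2 difference of -2.51 (SE 0.47). The D538G count was 4 when only the libraries compared were fitted. It was 3 and 174 without Gertz D538G E2 replicate 1 and 2, 54 and 79 without Gertz WT E2 replicate 1 and 2, 114 and 59 without Oesterreich WT E2 replicate 1 and 2, and 1525 and 600 without Oesterreich D538G E2 replicate 1 and 3. The split was 58 higher against 19271 lower with total coverage scaling and 497 against 415 with the correction for coverage outside peaks.

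The mutant comparisons without E2 were finally repeated within the labs. Y537S had 36 higher and 4 lower regions in the Gertz clones and 290 and 435 in the Oesterreich clones, and D538G had 63 and 20 in the Gertz clones and 1181 and 2347 in the Oesterreich clones. For Y537S 12 regions were higher in the clones of both labs and 0 lower, where independent lists would share 0.288 and 0.048, and all 12 were E2-gained in WT. For D538G 21 were higher and 1 lower in both, where independent lists would share 2.05 and 1.30, and 18 of the 21 were E2-gained. Regions called in opposite directions numbered 1 and 4. The E2-gained list and the mutant calls share WT DMSO libraries, so part of this overlap can come from them. With E2-gained regions defined in the WT clones numbered 1 and the mutants compared with those numbered 2, 8 of the 10 regions higher in both labs for Y537S and 8 of the 18 for D538G were E2-gained, where independent lists would share 0.00828 and 0.0149. With the clone numbers exchanged both of the 2 regions for D538G were E2-gained, while for Y537S limma called 0 higher regions in the Gertz clones, against 1060 at an unadjusted p under 0.05, so that 0 were shared. With each lab fitted on its own libraries, Y537S had 199 higher and 101 lower regions in the Gertz clones and 29 and 20 in the Oesterreich clones, so that the order of the labs turned, and D538G had 384 and 193 in the Gertz clones and 453 and 732 in the Oesterreich clones. In those fits both labs shared 12 higher and 0 lower regions for Y537S, where independent lists would share 0.159 and 0.0557, and all 12 were E2-gained. For D538G they shared 20 higher and 9 lower, where independent lists would share 4.80 and 3.90, and 16 of the 20 were E2-gained. Opposite calls numbered 1 and 9. Tag extension followed genotype in the Oesterreich DMSO libraries, with 154 bp in both WT libraries, 107 and 100 bp in Y537S and 110, 111 and 102 bp in D538G. Counting recovered fragments, in which each tag counts once, gave 102 higher and 11 lower for Y537S and 146 and 33 for D538G in the Gertz clones, and 492 and 687 and 1474 and 2625 in the Oesterreich clones. The joint total of 34 became 52 and 8 without Gertz WT DMSO replicate 1 and 2, 19 without Gertz Y537S DMSO replicate 2, 14 and 15 without Gertz D538G DMSO replicate 1 and 2, and 22 without either Oesterreich WT DMSO library. Total coverage scaling gave 22 above and 38 below, limma voom on recovered fragments 39 and 35, array weights 71 and 23, and quantile normalization 48 and 4.

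Tests of the difference between labs called 100 regions for Y537S, 77 of them with the higher difference in the Gertz clones, and 868 for D538G, 561 of them higher in the Gertz clones. When only the libraries compared were fitted, 1121 were called for Y537S and 0 for D538G, with 5733 at an unadjusted p under 0.05 for D538G and 2475 called by limma voom on recovered fragments. The Y537S count was 4 without Gertz WT DMSO replicate 2, 8 and 3 without Gertz Y537S DMSO replicate 1 and 2, 15 and 25 without Oesterreich WT DMSO replicate 1 and 2, and 14 and 1 without Oesterreich Y537S DMSO replicate 1 and 2. The D538G count was 87 without Gertz WT DMSO replicate 2, 124 and 97 without Gertz D538G DMSO replicate 1 and 2, and 211 and 186 without Oesterreich WT DMSO replicate 1 and 2. Total coverage scaling gave splits of 512 against 50 and 14264 against 62, and quantile normalization gave 313 against 163 for Y537S. The WT clones of the labs themselves differed without E2 at 6914 regions, 3179 higher in Gertz and 3735 higher in Oesterreich, and at 900 after a correction for coverage outside peaks. Without Gertz WT DMSO replicate 1 and 2 that count was 4004 and 2559, without Oesterreich WT DMSO replicate 1 and 2 it was 3644 and 2464, and total coverage scaling, which moved the median by 0.29, gave 7519 against 2544. The first principal component, with 33.5% of the variance, separated the labs.

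**Figure D4:**
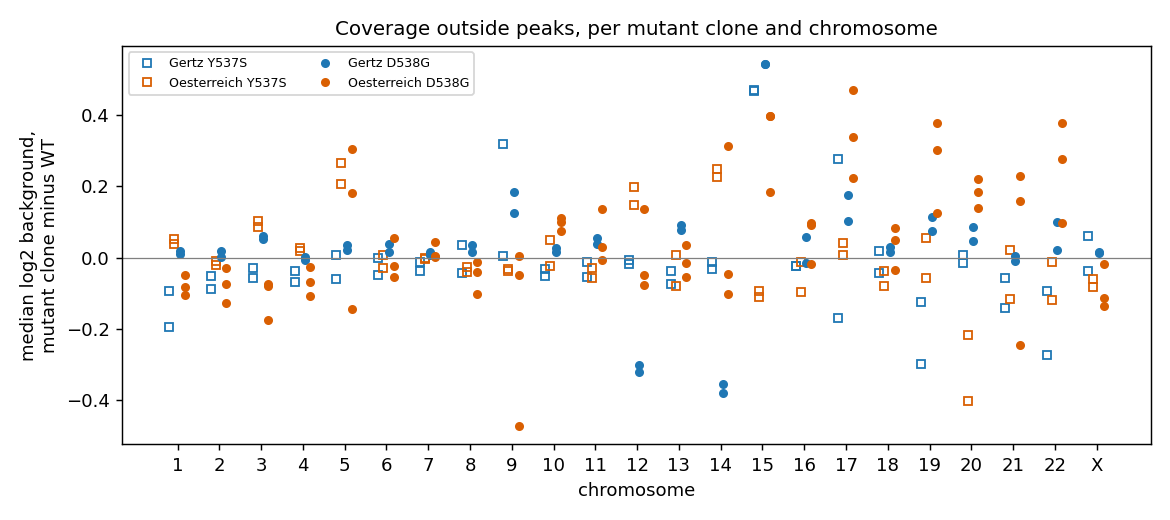
Median log2 difference in coverage outside peaks (vertical axis) between each mutant clone and the WT clones of its lab, for each chromosome (horizontal axis). Squares are Y537S and circles D538G. On chromosome 15 the Gertz Y537S clones sat at 0.47 and the Gertz D538G clones at 0.54.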

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

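The scalings and the copy number correction were alternatives set out beforehand, but their use as tests of the patterns below was decided after the results were seen. The tests of shared controls, recovered fragments and the comparisons of E2 responses, of both labs and of both mutants with divided WT clones were also chosen after the results were seen, and chromosome 15, with the difference between WT clones of the same lab as the level to exceed, was picked after its values were seen. The tests of matched random sets, of a smooth trend with coverage, of separate fits per lab and of other splits were set out beforehand.

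The E2 responses differed from WT by an interaction test at 7 regions in Y537S and 8 in D538G, and over the E2-gained regions by -1.16 and -0.94 on the log2 scale, in regions selected on the same WT libraries. In regions defined in other WT clones than those measured the differences were -1.31 and -1.05, or -1.435 and -1.22 with the clone numbers exchanged. By construction each is the difference from WT with E2 minus that without E2. In the first division these were 0.22 and 0.40 with E2 and 1.53 and 1.45 without E2. The mutant effects without E2 differed between labs at 100 regions for Y537S and 868 for D538G. Coverage outside peaks, which entered the comparisons only as a correction in an alternative, was raised on chromosome 15 in the Gertz Y537S clones by 0.470 and 0.467 and in the Gertz D538G clones by 0.542 each (0.5418 and 0.5422), where the Gertz WT clones differed by 0.019. In the Oesterreich Y537S clones it was -0.09 and -0.11. The Oesterreich WT clones themselves differed by 0.48 on that chromosome, a level that the Gertz D538G clones exceeded and the Gertz Y537S clones did not. The 868 became 0 when only the libraries compared were fitted.

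Regions gained with E2 in WT were more open in both mutants without E2. Shared WT controls are argued against by the divided clones, where the lowest mean was 1.27. Other scalings left at least 1.00 and the copy number correction at least 1.55. The highest mean of 1000 random sets matched on coverage and breadth was 0.27. Receptor activity without hormone may account for the pattern, but it stays a hypothesis that no test here addressed, since motif searches and gene lists were not run; extension length was tested only by recovered fragments (1.48 and 1.47).

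D538G calls without E2 gathered on chromosomes 12, 14 and 15. After subtracting coverage outside peaks the medians moved from -0.17, -0.17 and 0.32 to 0.02, 0.06 and -0.10 (-0.099, barely within the 0.1 set as a bound), so copy number of the clones may account for the shift. The correction left 5 higher and 24 lower regions on chromosome 15, where it may have overcorrected, which was not tested. Coverage outside peaks also varied on chromosomes 17, 19 and 22, with 0.22, 0.34 and 0.47 on chromosome 17 in the Oesterreich D538G clones, so it may hold more than copy number, which no test here separated, and GC content was not analysed here.

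D538G differed from WT at 83 regions in the Gertz clones and 3528 in the Oesterreich clones. Removing a smooth trend with coverage left 61 and 3007, so that trend alone does not account for the gap. The test does not remove noise of single regions, so it cannot decide on lower enrichment. Clones of a group correlated with r of 0.69 to 0.77 in Oesterreich D538G with DMSO. In the other DMSO groups r was 0.81 to 0.89. With each lab fitted on its own libraries the counts were 577 and 1185, so one estimate of the spread for both labs may account for much of the gap. Recovered fragments, in which each tag counts once, gave 179 and 4099 with one estimate of the spread. Lower enrichment, clone number, depth and differences between the clones of the labs stay open.

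The libraries of each comparison were also split in other ways, with the lab as a term and only those libraries fitted with limma. For Y537S against WT without E2 only the real groups called as many regions (96, highest other split 28, 1 of 34 splits as large). That is the smallest share these splits can give, and it was not adjusted for the number of comparisons. The real counts of these fits are not those of the main fit. It called 158 regions here, 653 for D538G against WT and 130 for D538G against Y537S. For D538G against WT and against Y537S without E2 3 of 100 splits each called as many. The real values were 10 and 6 and the highest others 820 and 2051. Those highest splits set 1 Oesterreich D538G clone apart from the rest of its lab and point to a structure of those libraries. The share therefore does not exclude chance there. Chance could not be excluded for Y537S with E2 (21, highest other 55, 2 of 34). Where the real count in these fits was 0, every split is as large by construction and the splits decide nothing: E2 in Y537S (highest other 9, 34 of 34), E2 in D538G (highest other 15, 100 of 100), D538G with E2 (highest other 1189, 100 of 100), and the differences in E2 response of Y537S (highest other 0, 34 of 34) and D538G (highest other 2101, 100 of 100). For E2 in WT 124 regions were called, the highest other split called 15 and 1 of 34 splits was as large, but those splits set aside that DMSO and E2 libraries are paired by clone. Only 8 splits part every clone's libraries, of which the highest other called 8, and these are too few for a share under 0.05.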

How the results depend on the processing

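The recovered fragments (also within each lab), voom, the regions shared by labs with each lab on its own libraries, the comparisons with divided WT clones, the fit without Oesterreich D538G clone 2 and the fit without chromosomes 12, 14 and 15 were chosen after seeing the data. Counts are of called regions, and the cause of a change was not tested except where fewer libraries or regions were fitted by construction. The mean difference of the E2-gained regions kept its direction and its call in all 29 alternatives run for Y537S (means 0.90 to 2.37) and all 31 for D538G (0.86 to 2.09), with 3 to 126 regions as the set was redefined each time. Scaling by total coverage gave 3622 for Y537S against WT without E2, 17186 for D538G against WT without E2, 3078 for D538G against Y537S without E2, 318 for Y537S against WT with E2, 19329 for D538G against WT with E2, 562 for the Y537S lab difference, 14326 for the D538G lab difference, 60 for regions shared by labs and 3287 for regions shared by mutants. Quantile normalization gave 32 for E2 in D538G, 620 for Y537S against WT without E2, 518 for D538G against Y537S without E2, 378 for Y537S against WT with E2, 476 for the Y537S lab difference, 52 for regions shared by labs and 165 for regions shared by mutants. A pseudocount of 0.01 of the median gave 66 for D538G against Y537S without E2, 2 for Y537S against WT with E2, 161 for D538G against WT with E2, 60 for the Y537S lab difference and 553 for the D538G lab difference. A pseudocount of 0.5 of the median gave 67 for E2 in D538G, 253 for Y537S against WT without E2, 241 for D538G against Y537S without E2, 21 for Y537S against WT with E2, 635 for D538G against WT with E2, 3 for the D538G difference in E2 response, 301 for the Y537S lab difference and 1342 for the D538G lab difference. Leaving out the regions of lowest coverage gave 2 for Y537S against WT with E2. Peaks of at least 6 libraries gave 7 for Y537S against WT with E2 and 167 for the Y537S lab difference. 500 bp windows at the summit gave 225 for E2 in WT, 47 for E2 in D538G, 382 for Y537S against WT without E2, 1042 for D538G against WT without E2, 347 for D538G against Y537S without E2, 66 for Y537S against WT with E2, 750 for D538G against WT with E2, 16 for the Y537S difference in E2 response, 364 for the Y537S lab difference, 1598 for the D538G lab difference, 64 for regions shared by labs and 163 for regions shared by mutants. Requiring peaks over at least 0.5 of a region gave 2 for Y537S against WT with E2. Limma array weights gave 237 for E2 in WT, 9 for E2 in Y537S, 1539 for Y537S against WT without E2, 1309 for D538G against WT without E2, 1349 for D538G against Y537S without E2, 714 for Y537S against WT with E2, 26 for the Y537S difference in E2 response, 1328 for the Y537S lab difference, 1798 for the D538G lab difference, 94 for regions shared by labs and 362 for regions shared by mutants. The copy number correction gave 4 for E2 in D538G, 217 for D538G against Y537S without E2, 2 for Y537S against WT with E2, 912 for D538G against WT with E2, 5 for the D538G difference in E2 response and 900 for the WT labs. Fitting only the libraries compared gave 0 for E2 in D538G, 1111 for Y537S against WT without E2, 65 for D538G against WT without E2, 17 for D538G against Y537S without E2, 514 for Y537S against WT with E2, 4 for D538G against WT with E2, 14 for the Y537S difference in E2 response, 2 for the D538G difference in E2 response, 1121 for the Y537S lab difference and 0 for the D538G lab difference. The replicate block gave 20 for E2 in D538G, 13 for the Y537S difference in E2 response, 346 for Y537S against WT without E2, 1094 for D538G against WT without E2, 505 for D538G against Y537S without E2, 20 for Y537S against WT with E2, 614 for D538G against WT with E2, 265 for the Y537S lab difference, 54 for regions shared by labs and 139 for regions shared by mutants. The replicate block with the copy number correction gave 298 for Y537S against WT without E2, 1115 for D538G against WT without E2, 564 for D538G against Y537S without E2, 11 for Y537S against WT with E2, 1280 for D538G against WT with E2, 237 for the Y537S lab difference and 119 for regions shared by mutants. Gertz clones alone gave 1 for E2 in D538G, 40 for Y537S against WT without E2, 83 for D538G against WT without E2, 2 for D538G against Y537S without E2, 19 for D538G against WT with E2, 1 for the Y537S difference in E2 response, 0 for the D538G difference in E2 response and 24 for regions shared by mutants. Oesterreich clones alone gave 11 for E2 in WT, 46 for E2 in D538G, 725 for Y537S against WT without E2, 3528 for D538G against WT without E2, 1191 for D538G against Y537S without E2, 47 for Y537S against WT with E2, 2509 for D538G against WT with E2, 1 for the Y537S difference in E2 response, 2 for the D538G difference in E2 response and 442 for regions shared by mutants. Recovered fragment centres in 500 bp windows gave 36 for E2 in D538G, 369 for Y537S against WT without E2, 1029 for D538G against WT without E2, 317 for D538G against Y537S without E2, 68 for Y537S against WT with E2, 696 for D538G against WT with E2, 15 for the Y537S difference in E2 response, 365 for the Y537S lab difference, 1543 for the D538G lab difference, 64 for regions shared by labs and 161 for regions shared by mutants. Limma voom on recovered fragments gave 243 for E2 in WT, 25 for E2 in Y537S, 91 for E2 in D538G, 1666 for Y537S against WT without E2, 1494 for D538G against WT without E2, 1320 for D538G against Y537S without E2, 1739 for Y537S against WT with E2, 726 for D538G against WT with E2, 21 for the Y537S difference in E2 response, 1847 for the Y537S lab difference, 2475 for the D538G lab difference, 74 for regions shared by labs and 449 for regions shared by mutants. Leaving out both Oesterreich D538G clone 2 libraries gave 39 for E2 in D538G, 1327 for D538G against WT without E2, 387 for D538G against Y537S without E2, 873 for D538G against WT with E2, 2018 for the D538G lab difference and 197 for regions shared by mutants. Gertz clones alone on recovered fragment centres gave 179 for D538G against WT without E2. Oesterreich clones alone on recovered fragment centres gave 1179 for Y537S against WT without E2 and 4099 for D538G against WT without E2.

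Leaving out each library in turn gave 79 to 194 for E2 in WT, 0 to 0 for E2 in Y537S, 1 to 54 for E2 in D538G, 35 to 356 for Y537S against WT without E2, 127 to 960 for D538G against WT without E2, 11 to 335 for D538G against Y537S without E2, 0 to 2 for Y537S against WT with E2, 3 to 1525 for D538G against WT with E2. For the remaining results the ranges were 4 to 13 for the Y537S difference in E2 response, 2 to 16 for the D538G difference in E2 response, 1 to 91 for the Y537S lab difference, 87 to 1242 for the D538G lab difference, 2464 to 4004 for the WT labs, 1.43 to 2.15 for the E2-gained regions in Y537S, 1.06 to 2.09 for the E2-gained regions in D538G, 8 to 52 for regions shared by labs, 21 to 167 for regions shared by mutants. A group left with 1 library was assumed to vary like the others. Clone numbers of different genotypes share only a number: their deviations correlated with r between -0.09 and 0.06, over 0.1 in 0 of 12 pairs, and the block there changed the counts as given. Where both groups held 2 clones, the same r counts for both pairs by construction. For E2 comparisons the block is the clone, and beyond those counts it moved no other count by over 1.5 times (186 for E2 in WT, 0 for E2 in Y537S and 11 for the D538G difference in E2 response). For WT clones compared between the labs no paired analysis was possible because the clone numbers lie within a lab. Of the named regions none reversed under an alternative; the values that kept their side of the threshold were 222 of 243 for E2 in WT, 62 of 109 for E2 in D538G, 412 of 518 for Y537S against WT without E2, 486 of 552 for D538G against WT without E2, 102 of 156 for D538G against Y537S without E2, 21 of 26 for Y537S against WT with E2, 109 of 156 for D538G against WT with E2, 91 of 99 for the Y537S difference in E2 response, 79 of 108 for the D538G difference in E2 response. Alternatives for the gene lists and motif sets were not run. At the E2-gained regions the difference of Y537S from WT with E2, which did not pass, turned from -0.01 to 0.22 with regions defined in the WT clones numbered 1 and measured against those numbered 2. No library was thinned to test what depth limits: the shallowest held 1399208 tags, and the Oesterreich D538G libraries had the lowest share of coverage in regions.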

Other observations

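Peaks called with E2 covered 74.3% ± 10.8 (SD, n = 4) of the E2-gained regions in Y537S and 42.4% ± 43.4 (SD, n = 5) in D538G. The share was higher than with DMSO in every Y537S clone, in both Gertz D538G clones and in Oesterreich D538G clone 1 (8.78% with DMSO and 27.7% with E2). It was 2.03% with both in Oesterreich D538G clone 2, and 8.78% with DMSO and 5.41% with E2 in clone 3. Over all regions the share with a peak was also higher with E2 in 3 of the 4 Y537S clones (55.0% to 70.9%, 49.1% to 75.2% and 49.9% to 67.8%) and lower in the other (71.3% to 47.6%). In D538G it was 36.3% ± 28.9 with DMSO and 24.3% ± 17.8 with E2 (SD, n = 5 each). In the Gertz D538G clones the mean log2 level with E2 was 2.77 above WT DMSO, and in the Oesterreich D538G clones it was 1.28, where a peak was called at 11.7% of the regions. Of the 385 regions lower in D538G 234 had a peak in 16 to 25 libraries, as did 10337 of the 36240 tested, and 9 had one in all 26, as did 1623 of those tested. These shares were not tested.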
